A study of Mus musculus with 18 samples.

How the data were processed

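Expression was measured in 18 mouse libraries by SC3-seq, a 3' RNA sequencing method that reads transcript ends, from cDNA amplified out of 1 ng of RNA per the labels. The labels place the libraries in 9 groups of 2 replicates. For the cultured groups the labels' protocols call the replicates biological. For ESCs, EpiLCs and uncultured day-4 PGCLCs nothing says that they came from separate cultures, so the spread between those samples may be technical. P-values there rest on a spread estimated from all 18 libraries, the cultured ones included. They do not measure the spread between those samples alone.

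The deposited values are RPM, read numbers scaled by the authors to a common library total, with 1 value per gene and library and no correction for transcript length. The unit was read from the file naming and from the values, whose total per library lies between 999098 and 999617. The submitters' processing notes name cutadapt 1.3, TopHat 1.4.1, Cufflinks 2.2.0 and the genome build mm10, without saying how each was used. The gene annotation and the counting settings are not given in the sources used here. Each file lists 34896 genes by symbol and NCBI gene number, of which 46 have no value and were left out. SC3-seq reads only the ends of transcripts, so RPM is set by transcript number and not by transcript length, but genes with near-identical 3' ends can share reads. Because RPM is a share of each library, a rise of abundant genes lowers every other gene.

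The number of reads behind each library was inferred from the step between its low RPM values. With a tolerance of 0.02 read, 99.6% to 99.9% of low values were whole multiples of that step. In each library 32 to 55 values lay far below the step, so the values were not treated as whole reads and no count model was the main test. The inferred depth ran from 2129326 to 7547917 reads. At these depths 3 reads correspond to 0.397 to 1.41 RPM, and between 6803 and 7842 genes reached 10 RPM per library. Depth in this sense covers counting error only, since amplified reads without molecular identifiers are not independent molecules.

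Genes that reached 10 RPM in at least 2 libraries were tested, which left 9561. Values were taken as log2(RPM + 1), and a fold change on that scale understates the change of a gene with low values. All 18 libraries entered a limma fit with a mean per group and an empirical Bayes variance trend, with 9 residual degrees of freedom. The median residual SD was 0.37 on the log2 scale. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, and adjusted p-values of genes throughout are from limma. The comparisons, their tests, the gene lists and the rule for naming genes were fixed before the data were examined.

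In all, 32 gene lists with 541 genes were written, of which 535 are in the files and 396 were tested. The 6 others were not analysed here. A list with at least 4 tested members, which held for 29, was tested with camera in limma at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. This compares the list with all other genes. The calls were repeated with a correlation estimated for each list, which is the stricter reading, and with fry, which asks only whether a list's genes move together in 1 direction on balance. Several lists share members, so they are not independent of each other.

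Genes are named by this rule. In each comparison they are the 8 higher and 8 lower called genes with the largest change whose groups do not overlap, leaving out names given only as predicted or clone genes, microRNAs and small nucleolar RNAs. To these come up to 4 called members of each list by smallest p, or up to 2 uncalled members as values where fewer than 2 were called. A fixed panel of germ cell, FGF and calcineurin genes was followed in every comparison, and where fewer than 5 genes were called in a direction the 5 with the smallest p were allowed as values. Not every gene the rule allows is named.

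The procedure was tested on simulated data with 200 of the 9561 genes changed. In the comparison of CsA with FR10 in cultured PGCLCs it recovered 16.5% of 2-fold changes, 95% of 4-fold changes and 99% of 8-fold changes. The corresponding shares were 14%, 91% and 100% for FGF2 against FR10, and 22%, 93.5% and 99.5% for CsA against FR10 in cultured embryo cells. A change of 2-fold was therefore mostly below what 2 libraries per group could show. The changed genes were drawn only from tested genes with a higher mean RPM, so recovery among tested genes with low values was not measured. The simulation gave every group the same spread per gene. Over the tested genes the median absolute log2 difference between replicates was 0.193 in ESCs. It was 0.468 in d4c7 FGF2, 0.426 in E9.5c5 FR10 and 0.601 in E9.5c5 CsA. The recovered shares may be too high for those groups, where an absence of calls does not exclude 4-fold changes.

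Alternatives were pseudocounts of 0.1 and 10 RPM, no filter and a filter at 50 RPM, median-ratio scaling of libraries, the replicate number as a block, no variance trend, a 2-fold minimum, fits on the 12 cultured or the 6 other libraries alone, and leaving out each replicate. Further alternatives were added after the data were seen and are named as such where they appear. The most consequential of these leaves out 3 libraries, replicate 2 of d4c7 FGF2, of E9.5c5 FR10 and of E9.5c5 CsA, whose distance from their own replicates was the largest of the 9 pairs. That fit was chosen after the data were seen, lowers the estimated spread and raises most counts. Gene positions are from the GRCm38.p6 annotation, the assembly behind mm10, matched by NCBI gene number. The work used R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.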

Results

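Primordial germ cell-like cells (PGCLCs) are the germline precursors obtained in vitro from embryonic stem cells (ESCs) by way of epiblast-like cells (EpiLCs). The series concerns the growth and survival of such cells in culture with cyclosporin A (CsA), an inhibitor of the phosphatase calcineurin, and with FGF signalling. It holds ESCs, EpiLCs and PGCLCs at day 4 of induction, the last sorted for a Blimp1-mVenus reporter. Day-4 PGCLCs were also cultured for 7 days on m220-5 feeder cells and sorted again (d4c7). Primordial germ cells of E9.5 embryos carrying a Stella-EGFP reporter were cultured for 5 days and sorted for EGFP (E9.5c5). The culture medium contained stem cell factor, 10 µM forskolin and rolipram, agents that raise cAMP, and this condition is called FR10. The protocol does not say whether these agents were also in the CsA and FGF cultures. The d4c7 groups were FR10, CsA, FGF10 and FGF2, and the E9.5c5 groups were FR10 and CsA. FGF10 and FGF2 are the names in the labels. Whether FGF10 names a growth factor or an amount of FGF, and the doses of these additions and of CsA, are not given in the sources used here, so the comparison of FGF2 with FGF10 is of groups as labelled. Each of the 9 groups had 2 libraries, with an inferred depth of 2129326 to 7547917 reads.

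The libraries were not equally repeatable. Among 413 abundant genes the median absolute log2 difference between replicates was at most 0.163 in 6 groups. It was 0.284 in d4c7 FGF2, 0.293 in E9.5c5 FR10 and 0.499 in E9.5c5 CsA. In each of these 3 groups replicate 2 had fewer detected genes than replicate 1 at equal read number, 12449, 12810 and 12190 in replicate 2. These replicate 2 libraries are the 3 libraries left out where a count without 3 libraries is given. The first 4 principal components held 39.95%, 17%, 10.19% and 8.74% of the variance.

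EpiLCs, the state reached on day 2 of induction, were compared with ESCs to show which genes changed on leaving the naive state. Of 16 tested naive pluripotency genes, 14 fell and 0 rose, with a median log2 fold change of −4.04. Klf2, a transcription factor of the naive state (chromosome 8, 72319062 to 72321654, GRCm38.p6), fell from 118 ± 1.61 to 0.479 ± 0.131 RPM (SD, n = 2). Esrrb (log2 fold change −5.72 ± 0.30, SE), Tfcp2l1 (−6.03 ± 0.32) and Tdh (−7.48 ± 0.36), which encodes a threonine-degrading enzyme, fell with it. Of 15 formative and primed epiblast genes, 12 rose and 0 fell, with a median of 3.67. Sox4 rose by 6.26 ± 0.36, Pim2 by 5.43 ± 0.40, and the de novo DNA methyltransferase genes Dnmt3a and Dnmt3b by 4.25 ± 0.40 and 3.67 ± 0.32. Fgf5 was listed at 0 in both ESC libraries and at 47.4 ± 1.88 RPM in EpiLCs. Early germ cell genes went down, with 9 of 13 lower and 0 higher, among them Tfap2c (−4.82 ± 0.26), Prdm14 (−4.92 ± 0.31), Tcl1 (−6.21 ± 0.28) and Dppa3 (−2.69 ± 0.24). Sox2 fell by 3.19 ± 0.24, while Pou5f1 differed by 0.01 ± 0.20 with an adjusted p of 0.98 and changed sign without ESC replicate 1 (−0.008) or EpiLC replicate 2 (−0.04).

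Of 19 FGF and MAPK response genes, 5 rose and 0 fell in EpiLCs, with Dusp4 (4.38 ± 0.23), Myc (3.88 ± 0.59), Dusp6 (3.01 ± 0.62) and Etv4 (1.91 ± 0.40) among them. ESCs had been kept with an inhibitor of MEK and EpiLCs with FGF2, per the labels' protocols. Of 18 oxidative stress response genes, 7 fell and 1 rose, including Hspb1 (−3.05 ± 0.39), a small heat shock protein, Sod2 (−1.70 ± 0.22) and Gpx1 (−1.02 ± 0.18). In camera the naive, primed and early germ cell lists had adjusted p-values of 1.35e-22, 4.60e-16 and 4.00e-13, and of 0.000388, 0.000242 and 0.00124 with an estimated correlation. The FGF and MAPK list had 0.000218 and the oxidative stress list 0.0134, and with an estimated correlation these became adjusted p-values of 0.0863 and 0.152. Adjusted over the list alone, 14 naive genes fell and 1 rose, 13 primed genes rose and 10 early germ cell genes fell. Feeder and fibroblast markers were called in both directions, 4 higher and 1 lower of 13, with Cxcl12 higher by 4.43 ± 0.79 and Sparc lower (−2.96 ± 0.22). In all, 1525 of 9561 genes were called by limma, 678 higher and 847 lower. Without ESC replicate 1 or 2 the count was 840 and 880, and without EpiLC replicate 1 or 2 it was 942 and 826. Leaving out the 3 libraries named above raised it to 2821.

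Day-4 PGCLCs were compared with the EpiLCs they were induced from. All 13 tested early germ cell genes rose, with a median log2 fold change of 4.96. Tfap2c, which encodes a transcription factor of germ cell specification (chromosome 2, 172545678 to 172558622), went from 0.286 ± 0.404 to 206 ± 0.569 RPM (SD, n = 2), a log2 change of 7.37 ± 0.26. Prdm14 rose by 6.80 ± 0.31, Prdm1 by 6.75 ± 0.43, Kit by 5.41 ± 0.25, Dppa3 by 4.61 ± 0.24 and Nanos3 by 3.40 ± 0.38. Prdm1 is the gene whose reporter was used to sort these cells, so its level is not independent of the sort. Of 15 formative and primed genes, 12 fell and 3 rose. Dnmt3b fell from 1383 ± 44.2 to 3.19 ± 0.14 RPM (SD, n = 2), and Pou3f1 (−6.35 ± 0.76), Otx2 (−4.82 ± 0.46) and Pim2 (−5.44 ± 0.40) fell with it. Dnmt3a (−3.46 ± 0.40), Dnmt3l (−5.12 ± 0.58) and Uhrf1 (−3.40 ± 0.41), a cofactor of maintenance methylation, were also lower. Of 16 naive genes, 11 rose and 2 fell, with Klf2 (6.47 ± 0.25), Tdh (7.03 ± 0.36) and Esrrb (5.00 ± 0.30) among the risers. All 4 tested mesoderm and somatic genes rose. Id1, a target of BMP signalling, rose by 3.39 ± 0.57, and Msx2, Cdx1 and Evx1 were listed at 0 in both EpiLC libraries.

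Cholesterol synthesis genes had 11 of 19 lower and 0 higher in day-4 PGCLCs, with Fdps (−2.28 ± 0.20), Nsdhl (−1.78 ± 0.30) and Cyp51 (−1.91 ± 0.33). Endoplasmic reticulum (ER) and amino acid stress genes had 12 of 18 lower and 1 higher, including Trib3 (−4.49 ± 0.46), Atf4 (−1.89 ± 0.20) and Herpud1 (−3.25 ± 0.41). Glycolysis and hypoxia genes had 10 of 19 lower and 2 higher, among them the glucose transporter gene Slc2a1 (−1.89 ± 0.29), Tpi1 (−2.01 ± 0.32) and Pfkl (−2.86 ± 0.45), and the list had an adjusted p of 0.149 with an estimated correlation. Later germ cell genes had 7 of 15 lower and 0 higher, with Sycp3 (−4.34 ± 0.64) and Hormad1 (−2.33 ± 0.57). Histone modification enzymes had 8 of 18 higher and 0 lower, with Kdm3b (2.58 ± 0.29), Jarid2 (1.79 ± 0.23) and Kdm3a (2.35 ± 0.32).

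Camera gave these comparisons adjusted p-values of 1.86e-16 for early germ cell, 5.47e-10 for primed, 2.26e-07 for cholesterol, 2.60e-06 for ER stress and 0.00167 for mesoderm genes. With an estimated correlation these lists had adjusted p-values of 0.000851, 0.000851, 0.00389, 0.00363 and 0.0357. The calls of glycolysis (1.15e-05), later germ cell (1.48e-05), naive (0.000124) and histone enzyme (0.0264) lists were lost there, at adjusted p-values of 0.149, 0.331, 0.051 and 0.185. Adjusted over the list alone, 13 cholesterol and 8 later germ cell genes fell. In all 3784 genes were called, 2629 higher and 1155 lower, and the median gene was 0.344 higher. With median-ratio scaling, which moved that median to 0.00165, 1667 were higher and 1796 lower, so the excess of higher genes holds only for RPM as deposited. Leaving out EpiLC replicate 2 or day-4 PGCLC replicate 1 gave 2413 and 2329 genes. EpiLCs were unsorted and PGCLCs sorted, a difference that goes with the comparison.

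Culture in FR10 was examined by comparing d4c7 FR10 cells with day-4 PGCLCs. Of 15 tested methylation-sensitive and later germ cell genes, 14 rose and 0 fell, with a median log2 fold change of 4.21. Dazl, which encodes a germ cell RNA-binding protein (chromosome 17, 50279393 to 50293620), went from 2.91 ± 0.797 to 802 ± 111 RPM (SD, n = 2), a log2 change of 7.69 ± 0.78. Fkbp6 rose by 5.55 ± 0.45, Gpat2 by 5.31 ± 0.52, Piwil2, of the piRNA pathway, by 3.48 ± 0.37 and Ddx4 by 3.16 ± 0.58. Among meiotic entry genes, Smc1b (3.96 ± 0.53), Hormad2 (2.47 ± 0.52) and Stra8 (3.90 ± 0.97) rose, though that list as a whole did not pass in any comparison. All 4 mesoderm genes fell, Evx1 (−4.42 ± 0.57), Msx2 (−4.39 ± 0.58), Cdx1 (−2.47 ± 0.46) and Id1 (−2.16 ± 0.57). Of 15 imprinted genes, 6 fell and 0 rose, led by Phlda2 (−3.80 ± 0.24), Meg3 (−3.40 ± 0.49), Igf2 (−3.20 ± 0.76) and Cdkn1c (−2.69 ± 0.65). Of 19 FGF and MAPK genes, 7 fell and 0 rose, with Spry4 (−2.65 ± 0.52), Etv5 (−1.26 ± 0.28) and Dusp4 (−0.88 ± 0.23). Tfap2c fell from 206 ± 0.569 to 72 ± 2.16 RPM (SD, n = 2), and Dppa3 rose by 1.10 ± 0.24. Prdm1 and Prdm14 did not pass, at −0.84 ± 0.43 and −0.89 ± 0.31. Dnmt3b rose by 2.48 ± 0.32, Lefty2 fell by 5.20 ± 0.41, and Id2 was listed at 0 in both FR10 libraries against 58.7 ± 18 RPM at day 4.

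Feeder and fibroblast markers also differed, with 7 of 13 higher and 1 lower after culture. Col3a1, a collagen gene of fibroblasts, was at 50.4 ± 26.3 RPM in d4c7 FR10 and 0.47 ± 0.664 RPM at day 4 (SD, n = 2), and Dcn was listed at 0 at day 4 and at 73 ± 5.15 RPM after culture. Sparc fell by 1.88 ± 0.22. In camera the later germ cell list had an adjusted p of 3.25e-19, mesoderm 0.000154, imprinted and feeder lists 0.00205 each and the FGF and MAPK list 0.0118. With an estimated correlation mesoderm genes passed, at an adjusted p of 0.045, while later germ cell (0.0648), imprinted (0.0543), feeder (0.638) and FGF and MAPK (0.263) lists had adjusted p-values that did not pass. Adjusted over the list alone, all 15 later germ cell genes rose and 8 imprinted genes fell. In total 1456 genes were called, 670 higher and 786 lower. Without day-4 replicate 1 or 2 the count was 573 and 727, and without FR10 replicate 1 or 2 it was 825 and 601. Leaving out the 3 libraries named above raised it to 2964. The labels give C57BL/6 for the day-4 cells and B6D2F1 for d4c7 cells, so strain and culture cannot be told apart.

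The first question of the culture series was what CsA changed. In d4c7 cells 3 genes were called with CsA relative to FR10. Sec61b, a subunit of the ER protein channel (chromosome 4, 47474661 to 47483233), rose from 596 ± 15.4 to 1379 ± 145 RPM (SD, n = 2), a log2 change of 1.20 ± 0.17 (adjusted p = 0.024). Hsp90b1, an ER chaperone (chromosome 10, 86690841 to 86705444), rose by 1.03 ± 0.16 (adjusted p = 0.038), and Dmtf1, a transcription factor of the cell cycle, fell by 1.81 ± 0.29 (adjusted p = 0.038). As a group, the 18 tested ER and amino acid stress genes were higher with a median of 0.64 (camera adjusted p = 8.90e-11, and adjusted p = 0.00101 with an estimated correlation). Of these, 1 passed over all genes and 4 rose adjusted over the list alone. Hspa5, the ER chaperone also called BiP, had a value of 1.31 ± 0.31 and Xbp1 of 1.08 ± 0.26, neither past the threshold over all genes. Manf, another ER stress gene, had 1.66 ± 0.31 (adjusted p = 0.059).

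FGF and MAPK response genes were lower with CsA as a group, with a median of −0.90 over 19 genes (camera adjusted p = 0.000237), but the call was lost at an adjusted p of 0.0975 with an estimated correlation. None passed over all genes, and 7 fell adjusted over the list alone. Etv4, a transcription factor gene induced by FGF signalling (chromosome 11, 101769747 to 101785310), was at 20.1 ± 4.99 RPM in FR10 and 6.61 ± 2.52 RPM in CsA (SD, n = 2), a log2 value of −1.49 ± 0.40 (adjusted p = 0.14). Spry1 had −1.64 ± 0.43 and Dusp6 −1.72 ± 0.62. Lower groups by camera were also histone modification enzymes (median −0.65, adjusted p = 0.00265) and G2 and M phase genes (−0.37, 0.0162). Higher ones were oxidative phosphorylation (median 0.27, adjusted p = 0.000754), oxidative stress (0.20, 0.0162) and p53 target genes (0.22, 0.0342). With an estimated correlation these 5 lists had adjusted p-values of 0.103, 0.634, 0.0852, 0.179 and 0.634. By camera without the 3 libraries named above p53 targets had 0.0589, while later germ cell and S phase genes passed, at 0.0297 each. In that fit the calls of later germ cell and S phase genes were lost with an estimated correlation (adjusted p = 0.445 and 0.303). Of the histone enzyme genes 4 fell adjusted over the list alone, and 1 gene of each of the oxidative phosphorylation and oxidative stress lists rose. Germ cell genes showed small values, Prdm1 −0.15 ± 0.43, Prdm14 0.04 ± 0.31, Tfap2c −0.04 ± 0.26 and Dppa3 0.09 ± 0.24, and Kit had −1.34 ± 0.25 (adjusted p = 0.059). Prdm1 (0.04) and Tfap2c (0.15) changed sign with median-ratio scaling, Tfap2c (0.03) also without CsA replicate 1, and Prdm14 without FR10 replicate 2 (−0.03) or CsA replicate 2 (−0.18). Rcan1, a transcriptional target of calcineurin signalling, had 0.35 ± 0.28, and 0 of the 16 tested calcineurin, NFAT and cyclophilin genes passed. Feeder markers had a median of −1.02 with 0 of 13 called, with Cxcl12 at −2.36 ± 0.79.

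The count of 3 was 0 without any 1 of the 4 libraries and 0 in a fit of the 12 cultured libraries alone, 7 with median-ratio scaling (6 higher, 1 lower), and 968 (175 higher, 793 lower) without the 3 libraries named above. The median of all genes was −0.236, and −0.0524 with median-ratio scaling.

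**Figure D1:**
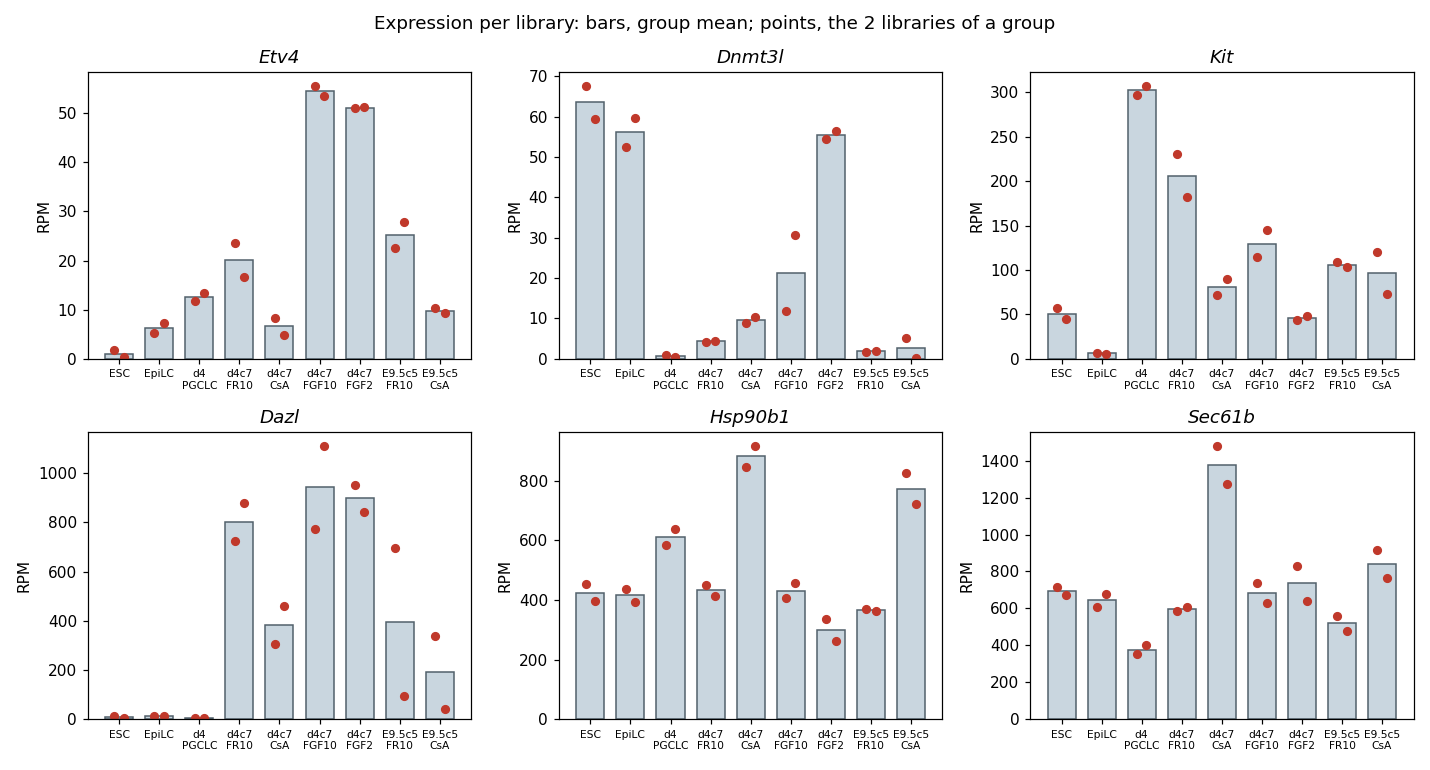
RPM of Etv4, Dnmt3l, Kit, Dazl, Hsp90b1 and Sec61b on linear axes that start at 0, for the 9 groups. Bars are group means and points are the 2 libraries of a group. Etv4 lay between 51 and 55.6 RPM in the 4 FGF libraries and at 8.39 and 4.83 RPM in the d4c7 CsA libraries, and Dazl differed between the replicates of E9.5c5 FR10, at 694 and 93.7 RPM.

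Cultured embryo cells gave a second view of CsA. In E9.5c5 cells limma called 0 genes between CsA and FR10, with 703 at an unadjusted p under 0.05 against 478 expected by chance. Replicates of both E9.5c5 groups lay further apart than those of most groups, but the p-values use a spread shared by all groups. They may be too small here, so the excess over 478 is no evidence of an effect. A voom fit on the inferred reads called 1. Hsp90b1 had the smallest p, with 774 ± 72.4 RPM in CsA and 367 ± 3.86 RPM in FR10 (SD, n = 2), and a log2 value of 1.07 ± 0.16 (adjusted p = 0.052). Hspa5 had 1.60 ± 0.31 and Manf 1.53 ± 0.31, both with an adjusted p of 0.18. ER and amino acid stress genes were higher as a group, with a median of 0.42 (camera adjusted p = 5.80e-08, and adjusted p = 0.00326 with an estimated correlation), and 4 of 18 rose adjusted over the list alone. Glycolysis and hypoxia genes were lower as a group (median −0.67, camera adjusted p = 1.59e-07), with 0 called over all genes and 7 lower adjusted over the list alone, Bnip3 having −1.42 ± 0.34 and Pkm −0.87 ± 0.23. This call had an adjusted p of 0.231 with an estimated correlation. Without the 3 libraries named above, which leaves 1 library in each E9.5c5 group, the glycolysis median was −0.45. Of germ cell genes, Prdm1 had 0.32 ± 0.43 and Dazl −1.12 ± 0.78, and both changed sign with single libraries left out, Prdm1 to −0.23 without FR10 replicate 2 and −0.11 without CsA replicate 1, and Dazl to 0.32 without FR10 replicate 1 and 0.41 without CsA replicate 2. Dazl was at 694 and 93.7 RPM in the FR10 replicates and at 339 and 40 RPM in the CsA replicates. FGF and MAPK genes (median −0.47, adjusted p = 0.0426), later germ cell genes (−0.57, 0.0426) and feeder markers (−0.88, 0.0429) were also lower by camera, and had adjusted p-values of 0.599, 0.844 and 0.844 with an estimated correlation. All 15 later germ cell genes were also lower in replicate 2 than in replicate 1 of both groups, with medians of −1.38 in FR10 and −1.24 in CsA. Without the 3 libraries the median was −0.25 for FGF and MAPK genes and −0.43 for feeder markers. Without E9.5c5 CsA replicate 1 the count was 654, without replicate 2 of that group it was 6, and without E9.5c5 FR10 replicate 1 it was 1. A count without the 3 libraries named above would compare 1 library with 1 and rest on the spread of other groups.

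Averaged over both cell origins, with 4 libraries a side, 13 genes were called between CsA and FR10, 9 higher and 4 lower with CsA. Hsp90b1 rose by 1.05 ± 0.12 (adjusted p = 0.000706), Sec61b by 0.95 ± 0.12, Manf by 1.60 ± 0.22, Hspa5 by 1.46 ± 0.22, Xbp1, a transcription factor of the unfolded protein response, by 0.99 ± 0.18, Serp1 by 0.86 ± 0.15 and Fkbp11 by 1.77 ± 0.34. Hspb1 rose by 1.52 ± 0.27. The lower genes were Tcfl5 (−2.43 ± 0.38), Lrrfip1 (−1.36 ± 0.26), Ppp4r2 (−0.85 ± 0.15) and Klhl13 (−0.80 ± 0.14). Of 18 ER and amino acid stress genes, 3 rose over all genes and 5 adjusted over the list alone (median 0.52, camera adjusted p = 2.23e-14, and adjusted p = 0.000317 with an estimated correlation). FGF and MAPK genes had a median of −0.70 with 0 of 19 called over all genes and 11 lower adjusted over the list alone (camera adjusted p = 6.94e-05, and adjusted p = 0.107 with an estimated correlation), with Etv4 at −1.38 ± 0.28 (adjusted p = 0.075) and Dusp4 at −0.62 ± 0.16. Rcan1 had −0.07 ± 0.20 (adjusted p = 0.9), and changed sign with median-ratio scaling (0.08) and without d4c7 FR10 replicate 2 (0.04), E9.5c5 FR10 replicate 1 (0.04), E9.5c5 CsA replicate 2 (0.14) or the 3 libraries named above (0.03).

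Feeder markers had a median of −1.06 in this averaged comparison, with 0 of 13 called (camera adjusted p = 0.0142, and adjusted p = 0.665 with an estimated correlation). Later germ cell (median −0.55, adjusted p = 0.0142), G2 and M phase (−0.36, 0.00562), histone enzyme (−0.39, 0.0133), glycolysis (−0.40, 0.0171) and S phase genes (−0.24, 0.0373) were lower by camera, and oxidative phosphorylation genes higher (0.06, 0.0162). With an estimated correlation these 6 lists had adjusted p-values of 0.711, 0.663, 0.202, 0.663, 0.663 and 0.202. Without the 3 libraries, which leaves 1 library in each E9.5c5 group, feeder and S phase lists did not pass by camera. In both E9.5c5 groups later germ cell genes differed more between replicates, with medians of −1.38 and −1.24. Genes that fell adjusted over the list alone were 6 of G2 and M phase, 3 later germ cell, 3 glycolysis, 1 histone enzyme and 1 feeder gene. The count of 13 was 4 without d4c7 FR10 replicate 1 or 2, 3 and 6 without d4c7 CsA replicate 1 or 2, 6 without E9.5c5 FR10 replicate 1 or 2 and 1126 without E9.5c5 CsA replicate 1. In the 12 cultured libraries alone it was 1, and without the 3 libraries named above 140. The median of all genes was −0.176, and −0.0401 with median-ratio scaling.

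The difference of the CsA effect between cell origins was tested directly. It called 0 genes, with 616 at an unadjusted p under 0.05 and 0 by voom, and 6 genes without E9.5c5 CsA replicate 1. Glycolysis and hypoxia genes differed as a group, with a median of −0.53 for E9.5c5 minus d4c7 (camera adjusted p = 3.23e-06), and so did oxidative phosphorylation genes (median −0.26, adjusted p = 0.0266). With an estimated correlation both had an adjusted p of 0.326, and 0 lists passed with fry. Etv4 had a difference of 0.21 ± 0.56, which changed sign without d4c7 FR10 replicate 1 (−0.03) or d4c7 CsA replicate 2 (−0.13).

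**Figure D2:**
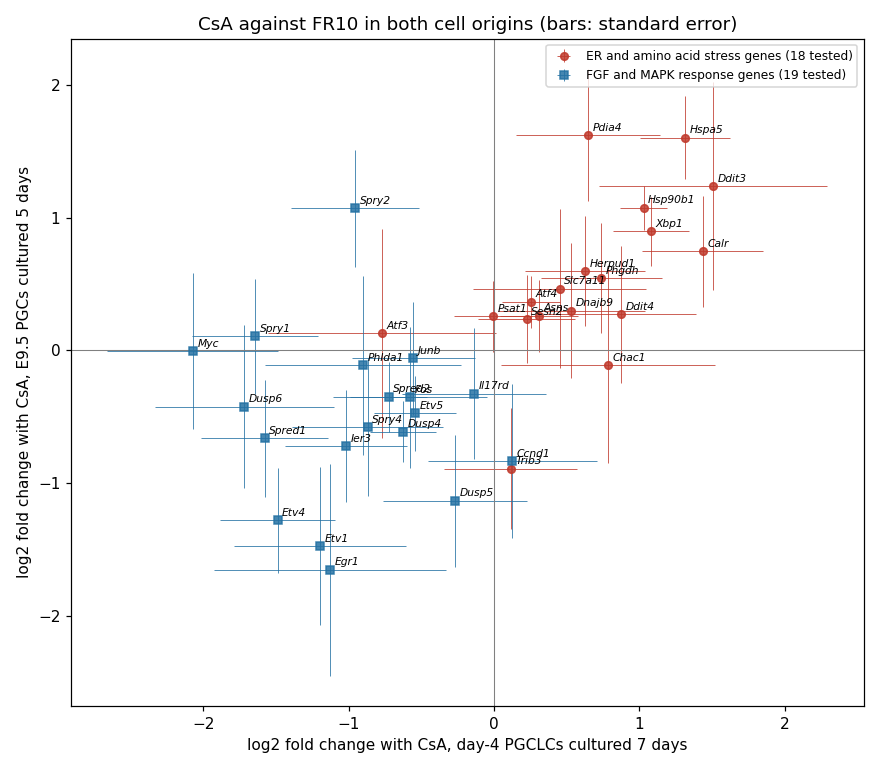
Log2 fold change with CsA in d4c7 cells (horizontal axis) and in E9.5c5 cells (vertical axis) for the tested ER and amino acid stress genes (circles) and FGF and MAPK response genes (squares), with standard errors as bars. Hsp90b1 lay at 1.03 and 1.07, and Etv4 at −1.49 and −1.28.

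The d4c7 groups labelled FGF10 and FGF2 were compared with FR10. With FGF10 limma called 0 genes, with 477 at an unadjusted p under 0.05 where 478 are expected by chance, and voom called 0. Etv4 was at 54.6 ± 1.47 RPM (SD, n = 2) and had a log2 value of 1.42 ± 0.40, and Dusp6 had −2.35 ± 0.62, both with an adjusted p of 0.69. Glycolysis and hypoxia genes were higher as a group (median 0.49, camera adjusted p = 7.28e-08, and adjusted p = 0.376 with an estimated correlation), with 0 of 19 called, Eno1 having 0.90 ± 0.30 and Pkm 0.64 ± 0.23. Leaving out the 3 libraries named above gave 2 higher and an adjusted p of 0.042 with an estimated correlation. Early germ cell genes were lower as a group (median −0.24, adjusted p = 0.0236, and adjusted p = 0.379 with an estimated correlation), with 0 of 13 called and Dppa3 at −0.68 ± 0.24. Without the 3 libraries named above, none of which belongs to either group, 36 genes were called.

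With FGF2, 845 genes were called relative to FR10, 131 higher and 714 lower. Dnmt3l, a cofactor of de novo DNA methylation (chromosome 10, 78042287 to 78063622), rose from 4.37 ± 0.162 to 55.4 ± 1.39 RPM (SD, n = 2), a log2 change of 3.39 ± 0.58 (adjusted p = 0.0071). Dnmt3b went from 22.8 ± 5.9 to 65.3 ± 0.825 RPM (SD, n = 2; adjusted p = 0.015). Bcat1, an enzyme of branched-chain amino acid metabolism, rose by 2.57 ± 0.35, Tead4 by 2.77 ± 0.52, Hspb1 by 2.46 ± 0.39 and Etv4 by 1.33 ± 0.40 (adjusted p = 0.047). Other FGF and MAPK genes went the opposite way, Dusp6 (−2.61 ± 0.62), Spred1 (−2.03 ± 0.44) and Spred2 (−1.13 ± 0.27), which encode inhibitors of the pathway, being lower, and the list did not pass as a group. Of the early germ cell genes Kit fell by 2.14 ± 0.25, Prdm1 by 2.04 ± 0.43 and Dppa3 by 1.00 ± 0.24, while Prdm14 (−0.91 ± 0.31) and Tfap2c (−0.43 ± 0.26) did not pass. Of 20 G2 and M phase genes, 6 fell and 0 rose, and 10 fell adjusted over the list alone, including Bub1 (−1.03 ± 0.20), Aurkb (−0.85 ± 0.19) and Top2a (−0.72 ± 0.18), and Pcna fell by 1.27 ± 0.23. Tcf4 fell by 3.20 ± 0.36. Among glycolysis and hypoxia genes Eno1 was the 1 called over all genes (1.04 ± 0.30), with 7 higher and 1 lower adjusted over the list alone, and among p53 targets Bbc3 rose by 1.80 ± 0.46. Of 13 feeder markers 3 fell and 0 rose, with Col3a1 at −3.83 ± 1.01, Cxcl12 at −3.50 ± 0.79 and Timp3 at −2.85 ± 0.73, and the list, with a median of −1.69, did not pass (camera adjusted p = 0.274). Leaving out the 3 libraries named above, which include FGF2 replicate 2, gave a feeder median of −0.70 with 1 of 13 lower.

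By camera, glycolysis (median 0.61, adjusted p = 3.79e-06), G2 and M phase (−0.72, 0.000964) and p53 target genes (0.28, 0.0314) passed for FGF2, and with an estimated correlation they had adjusted p-values of 0.669, 0.721 and 0.721. Glycolysis had a median of 0.30 (adjusted p = 0.0377) and G2 and M phase of −0.46 (0.00407) when the 3 libraries, FGF2 replicate 2 among them, were left out. The median of all genes was −0.326 and moved to −0.0836 with median-ratio scaling, which gave 530 genes, 224 higher and 306 lower. The count of 845 depended on single libraries. It was 5 without d4c7 FR10 replicate 1, 151 without FR10 replicate 2, 75 without d4c7 FGF2 replicate 2 and 1722 without FGF2 replicate 1. In the 12 cultured libraries alone it was 2, and without the 3 libraries named above it was 1094, of which 578 were among the 845.

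The FGF additions were also set against CsA. With FGF10, 60 genes were called relative to CsA, 47 higher and 13 lower. Of 19 FGF and MAPK genes, 4 rose and 0 fell, Etv4 by 2.91 ± 0.40, Myc by 3.04 ± 0.59, Spry1 by 2.37 ± 0.43 and Dusp4 by 1.32 ± 0.23 (camera adjusted p = 8.84e-05, and adjusted p = 0.111 with an estimated correlation). ER and amino acid stress genes were lower as a group (camera adjusted p = 3.28e-07, and adjusted p = 0.00472 with an estimated correlation), with 2 of 18 called, Hsp90b1 (−1.03 ± 0.16) and Hspa5 (−1.47 ± 0.31), and Manf fell by 1.54 ± 0.31. Dnmt3b rose by 1.78 ± 0.32 and Pfkp by 1.20 ± 0.25. Oxidative phosphorylation (0.00475), glycolysis (0.00782) and early germ cell lists (0.0169) passed by camera and had adjusted p-values of 0.111, 0.509 and 0.241 with an estimated correlation. Later germ cell and histone enzyme lists also passed by camera without the 3 libraries, at 0.0427 each, and lost the call there with an estimated correlation (adjusted p = 0.507 each). Adjusted over the list alone, 5 FGF and MAPK and 6 glycolysis genes rose and 2 early germ cell genes fell. With median-ratio scaling, which moved the median of all genes from 0.149 to 0.0153, 24 were higher and 18 lower. The count was 1 without CsA replicate 1, 25 without CsA replicate 2, 0 without either FGF10 library, 4 in the 12 cultured libraries alone and 1067 without the 3 libraries named above.

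With FGF2, 280 genes were called relative to CsA, 121 higher and 159 lower. Etv4 rose by 2.82 ± 0.40, Bcat1 by 3.24 ± 0.35, Dnmt3b by 2.16 ± 0.32 and Dnmt3l by 2.41 ± 0.58. Hsp90b1 (−1.57 ± 0.16), Hspa5 (−2.39 ± 0.31) and Herpud1 (−1.99 ± 0.41) fell, 3 of 18 ER stress genes, and so did 2 of 13 early germ cell genes, Prdm1 (−1.89 ± 0.43) and Dppa3 (−1.09 ± 0.24). Phlda2 fell by 1.93 ± 0.24, and of glycolysis genes Eno1 rose by 1.15 ± 0.30 and Pfkp by 0.96 ± 0.25. Glycolysis (0.000117), early germ cell (0.0039), ER stress (0.0039) and later germ cell lists (0.035, median 0.55) passed by camera, with adjusted p-values of 0.394, 0.204, 0.117 and 0.749 with an estimated correlation. Without the 3 libraries, which leaves 1 FGF2 library, the glycolysis median went from 0.70 to 0.22. That of FGF and MAPK genes went from 0.46 to 0.83. Of these lists 5 early germ cell and 4 ER stress genes fell adjusted over the list alone. The count was 13 and 23 without CsA replicate 1 or 2, 988 without FGF2 replicate 1, 31 without FGF2 replicate 2 and 3 in the 12 cultured libraries alone. Without the 3 libraries named above it was 500.

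Between FGF2 and FGF10, 9 genes were called, all lower with FGF2, among them Tcf4 (−3.06 ± 0.36), Lefty2 (−2.34 ± 0.41), Kit (−1.47 ± 0.25) and Dmtf1 (−1.95 ± 0.29). Etv4 differed by −0.09 ± 0.40, and by 0.11 with median-ratio scaling. G2 and M phase genes were lower as a group (median −0.50, camera adjusted p = 0.00113, and adjusted p = 0.728 with an estimated correlation). Of these 20 genes, 0 were called over all genes and 5 were lower adjusted over the list alone. Without the 3 libraries, which leaves 1 FGF2 library, the median was −0.32. The median of all genes was −0.232, and −0.0404 with median-ratio scaling, which called 5 genes. The count was 1 without either FGF10 library, 708 without FGF2 replicate 1, 4 without FGF2 replicate 2, 0 by voom and in the 12 cultured libraries alone, and 180 without the 3 libraries named above.

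The 3 comparisons with FR10 share its 2 libraries, so their fold changes correlate by chance. Across 9561 genes, which are not independent replicates, Pearson's r was 0.315 for CsA and FGF10, 0.409 for CsA and FGF2 and 0.601 for FGF10 and FGF2, where 100 simulations of unchanged groups gave 0.501, 0.50 and 0.50. The covariances were 0.0713, 0.154 and 0.202 against simulated values of 0.093, 0.0928 and 0.0928, that is differences of −0.0217, 0.0613 and 0.109. The differences were 0.0172, 0.093 and 0.127 without the 3 libraries named above, so that of CsA and FGF10 changed sign. The simulation, for r and covariance alike, used a spread pooled over all groups. None of the 3 libraries is from FR10, yet leaving them out lowered the simulated covariance of CsA and FGF10 from 0.093 to 0.0541. The measured one stayed at 0.0713. The differences thus depend on the spread of other groups and do not measure covariance beyond the shared libraries. With all libraries FGF10 had 0 genes called against FR10 by limma, and 0 of the 2 higher and 1 of the 1 lower gene with CsA were also called with FGF2. In the fit without the 3 libraries CsA and FGF2 shared 41 higher and 245 lower genes, where independent lists of those sizes would share 3.24 and 76.1. FGF10 and FGF2 then shared 11 of 15 higher and 14 of 21 lower FGF10 genes, against 0.278 and 2.01. CsA and FGF10 shared 2 and 3, against 0.275 and 1.74. The FR10 libraries are too few to be split, and part of any excess may come from them.

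Embryo-derived and induced cells were compared in the same medium. Between E9.5c5 FR10 and d4c7 FR10, 4 genes were called. Gdf3, a ligand of the TGF-beta family, was at 326 ± 45.6 RPM in E9.5c5 and 114 ± 11.7 RPM in d4c7 (SD, n = 2), higher by 1.51 ± 0.20 on the log2 scale (adjusted p = 0.0072). The imprinted gene Phlda2 was higher by 1.44 ± 0.24 and the ribosomal protein gene Rpl29 by 0.96 ± 0.16, whose family has many pseudogenes and which is therefore uncertain. Pfn1, encoding profilin, was lower (−1.20 ± 0.20). Early germ cell genes did not pass, with Dppa3 at 0.97 ± 0.24 (adjusted p = 0.16), Prdm14 at −0.28 ± 0.31 and Tfap2c at 0.01 ± 0.26, the last changing sign without d4c7 FR10 replicate 1 (−0.02) or E9.5c5 FR10 replicate 2 (−0.19). Dppa3 is also called Stella, the reporter used to sort the E9.5c5 cells only, so its level is not independent of the sort. Glycolysis genes were higher as a group (median 0.43, camera adjusted p = 0.000456, and adjusted p = 0.721 with an estimated correlation) and extraembryonic endoderm and trophoblast markers lower (median −1.32 over 4 genes, adjusted p = 0.0484, and adjusted p = 0.449 with an estimated correlation), in both lists with 0 genes called over all genes, and 2 extraembryonic markers lower adjusted over the list alone. The glycolysis median was 0.22 (adjusted p = 0.0182) with the 3 libraries, E9.5c5 FR10 replicate 2 among them, left out. With median-ratio scaling, which moved the median of all genes from −0.201 to −0.0515, 2 were higher and 0 lower. The count was 0 without either d4c7 FR10 library or E9.5c5 FR10 replicate 2, 259 without E9.5c5 FR10 replicate 1, 0 in the 12 cultured libraries alone and 31 without the 3 libraries named above. Strain, reporter and days in culture differ with the origin of the cells and cannot be told apart from it.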

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

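Of the tests in this part, those of library complexity, of feeder cells, of the share of higher genes with FGF2 and of the splits with all 18 libraries in the fit were chosen after the results were seen. The reading of the GC test was also tightened after its value was seen.

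By camera at the preset correlation, the response to CsA differed between cell origins for 2 gene lists, in the test of the difference itself. For glycolysis and hypoxia genes the E9.5c5 effect minus the d4c7 effect had a camera adjusted p of 3.234e-06, and for oxidative phosphorylation genes of 0.02663. With an estimated correlation both had an adjusted p of 0.3264, and 0 lists passed with fry. The list medians also moved between replicates of these groups. The largest moves were 0.322 for glycolysis genes in E9.5c5 FR10 and −0.505 for oxidative phosphorylation genes in E9.5c5 CsA. The difference between origins therefore rests on the preset correlation.

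Replicate 2 of d4c7 FGF2, of E9.5c5 FR10 and of E9.5c5 CsA stood apart from replicate 1. At equal read number they detected 12449, 12810 and 12190 genes, fewer than every other cultured library (lowest 13249, d4c7 CsA replicate 1), as low complexity would give. Low complexity alone was also predicted to leave abundant genes close. Yet among 413 abundant genes the smallest of the 3 differences was 1.74 times the largest of the other 6 pairs. How far low complexity moves genes of this abundance was not simulated, so it stays open. Against GC content of the 3' end, its correlations with the replicate difference of 0.219, 0.279 and 0.277 lay within the −0.123 to 0.285 of the other 6 pairs, but it cannot be told apart because d4c7 FR10 alone set that upper end, the next pair being at 0.0709. Feeder markers had median differences of −1.148 in d4c7 FGF2, −0.971 in E9.5c5 CsA and 0.079 in E9.5c5 FR10, and larger ones of −1.658 in d4c7 CsA and −2.035 in d4c7 FGF10, whose abundant genes differed by 0.117 and 0.147, which goes against feeder cells as the cause of the whole pattern, and a part stays open because in E9.5c5 FR10 the markers went both ways, 7 of 13 being higher. Ribosomal protein genes held 37.1%, 34.5% and 40.7% of RPM in replicate 2 of d4c7 FGF2, E9.5c5 FR10 and E9.5c5 CsA. In replicate 1 of these groups they held 33.2%, 32% and 30.9%. Whether that share bears on the pattern was not tested, nor were differences between the cultures themselves.

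ER and amino acid stress genes were higher as a group with CsA in each cell origin. Averaged over both origins, their median was 0.515, with 16 of 18 genes above 0. Feeder cells in the sort would have raised their own markers, whose median was −1.062 with 0 of 13 above 0. The list's median lay at percentile 100 of 10000 random lists matched on GC content, length and expression. Leaving out each of 8 libraries left that median between 0.451 and 0.693. Without E9.5c5 CsA replicate 1, 13 of 18 genes were above 0, and 16 or 17 without each other library. Of the 34 splits of the 8 libraries into 4 and 4, 1 gave a p as small, the real one (1.526e-16, smallest other 4.36e-10), which excludes chance only at the smallest share that 34 splits can give and without adjustment over the 9 lists split. An effect of CsA on the ER is a hypothesis that these values leave standing, found and tested on the same data.

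For the count of 13 genes in the averaged comparison, chance cannot be excluded. In the planned fit on the 8 libraries alone every one of the 34 splits gave 0 genes, the real one included, so that count tells nothing. With all 18 libraries in the fit 3 of 34 splits gave as many, and the highest other gave 946 genes. That split parted replicate 1 from replicate 2 of the E9.5c5 groups and also d4c7 FR10 from d4c7 CsA, so it holds the d4c7 part of the real contrast, and it points to a structure of the samples. Of the other 8 lists, FGF and MAPK (real 4.427e-06, smallest other 2.736e-05) and histone enzyme genes (0.002249, 0.004978) had a p as small in 1 of 34 splits, S phase and G2 and M phase genes in 2, oxidative phosphorylation in 4, feeder markers in 7, later germ cell genes in 12 and glycolysis genes in 14.

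With FGF2, 15.5% of changed genes were higher. Without the 3 libraries that stand apart the share was 16.2%, so they do not account for the excess of lower genes. With median-ratio scaling it was 42.3%, and ribosomal protein genes held 33.2% and 37.1% of RPM in the FGF2 libraries against 27.2% and 27.4% in FR10, and also 34% and 33.9% in d4c7 CsA, where the median of all genes was −0.236 and −0.0524 with that scaling. A few abundant genes taking more of the reads may therefore account for part of the excess. Whether the rise of those genes is itself a response to FGF2 was not tested.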

How the results depend on the processing

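The fits with library weights, with voom, without 3 libraries, with a block within E9.5c5 only and on the 8 d4c7 libraries were chosen after the data were seen, and the others were planned. Named genes gave 2789 values with the same direction and call as reported, 449 that lost the call, 77 that gained it and 22 that changed sign. Of 59 list calls, 13 held with an estimated correlation and 46 did not, and 31 held with fry and 28 did not. With median-ratio scaling 57 held, the others being G2 and M phase genes with CsA in d4c7 cells (adjusted p = 0.0659) and S phase genes in the averaged comparison (0.375). Without the 3 libraries 53 held. With 2 libraries a group, counts rest on few samples, and a left-out library leaves a lone sample that is assumed to vary like the other groups. Where counts moved the cause was not tested, except where the setting fixes it. Filters change which genes are tested. Leaving out a library of a compared group changes the fold changes. A fit without libraries of other groups keeps genes and fold changes, so only the estimated spread and its degrees of freedom differ. With the 12 cultured libraries alone, FGF2 against FR10 kept 9561 genes and a median of −0.326. The count there went from 845 to 2. The 8 d4c7 libraries alone, also without the uncultured ones, gave 447. The count of 845 thus depends on which other libraries enter the estimate of the spread.

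Counts that moved by more than 1.5 times follow. A pseudocount of 0.1 RPM gave 14 genes for FGF2 against FGF10 and 2 for CsA in E9.5c5, and one of 10 RPM gave 11 for CsA in d4c7 and 9 for E9.5c5 against d4c7. With no filter the counts were 2323 for EpiLC against ESC, 26 for CsA in d4c7, 25 for FGF10 and 495 for FGF2 against FR10, 33 for FGF2 against FGF10, 5 for CsA in E9.5c5, 27 for E9.5c5 against d4c7, 3 for CsA averaged and 1 for the difference between origins. At 50 RPM they were 851 for EpiLC against ESC, 2256 for day-4 PGCLC against EpiLC, 806 for FR10 against day 4, 21 for CsA in d4c7, 165 for FGF2 against CsA and 1 for CsA in E9.5c5. Median-ratio scaling gave 7 for CsA in d4c7, 530 for FGF2 against FR10, 5 for FGF2 against FGF10, 3 for CsA in E9.5c5 and 2 for E9.5c5 against d4c7. With no variance trend CsA in d4c7 gave 0, FGF10 against CsA 29 and CsA averaged 3, and with a 2-fold minimum CsA averaged gave 8. The 12 cultured libraries alone gave 0 for CsA in d4c7, 2 for FGF2 against FR10, 4 for FGF10 and 3 for FGF2 against CsA, 0 for FGF2 against FGF10, 0 for E9.5c5 against d4c7 and 1 for CsA averaged. The 6 other libraries alone gave 3262 for EpiLC against ESC and 5717 for day-4 PGCLC against EpiLC.

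Of the added fits, library weights gave 3466 for EpiLC against ESC, 2835 for FR10 against day 4, 474 for CsA in d4c7, 5 for FGF10 against FR10, 552 for FGF10 and 109 for FGF2 against CsA, 1 for FGF2 against FGF10, 10 for E9.5c5 against d4c7 and 6 for CsA averaged. These weights came out equal for both libraries of each group, so they weigh groups and do not single out a library. Voom gave 0 for FGF2 against FGF10 and 1 for CsA in E9.5c5. Without the 3 libraries the counts were 2821 for EpiLC against ESC, 2964 for FR10 against day 4, 968 for CsA in d4c7, 36 for FGF10 against FR10, 1067 for FGF10 and 500 for FGF2 against CsA, 180 for FGF2 against FGF10, 9 for CsA in E9.5c5, 31 for E9.5c5 against d4c7 and 140 for CsA averaged. The 8 d4c7 libraries alone gave 0 for CsA, 447 for FGF2 against FR10, 5 for FGF10 and 121 for FGF2 against CsA and 0 for FGF2 against FGF10.

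The labels do not tie same-numbered samples to a shared origin, and pairing by replicate number was not established. Over 36 pairs of groups the correlation of same-numbered deviations ran from −0.102 to 0.34 with a median of 0.00708, and 7 pairs lay above 0.1. The highest were E9.5c5 FR10 with E9.5c5 CsA (0.34), and d4c7 FGF2 with E9.5c5 CsA (0.257). With the replicate number as a block CsA in d4c7 gave 5, FGF2 against CsA 456, FGF2 against FGF10 16, CsA in E9.5c5 1 and E9.5c5 against d4c7 8, and 58 of the 59 list calls held, the other being extraembryonic markers (adjusted p = 0.0822). A block within E9.5c5 only, added later, gave 15 for CsA in E9.5c5, 440 for E9.5c5 against d4c7 (74 higher, 366 lower) and 197 for CsA averaged.

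Leaving out each library in turn gave 826 to 942 genes for EpiLC against ESC, 2329 to 2761 for day-4 PGCLC against EpiLC, 573 to 825 for FR10 against day 4, 0 for CsA in d4c7, 5 to 1722 for FGF2 against FR10, 0 to 25 for FGF10 and 13 to 988 for FGF2 against CsA, 1 to 708 for FGF2 against FGF10, 0 to 654 for CsA in E9.5c5, 0 to 259 for E9.5c5 against d4c7, 3 to 1126 for CsA averaged and 0 to 6 for the difference between origins.

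The changes of sign were all in genes not called. With median-ratio scaling, in d4c7 CsA Prdm1 had 0.037 and Tfap2c 0.148, Etv4 had 0.107 for FGF2 against FGF10 and Rcan1 0.075 for CsA averaged. Leaving out 1 library at a time, the log2 value of Pou5f1, EpiLC against ESC, ran from −0.041 to 0.071. With CsA in d4c7 Prdm14 ran from −0.18 to 0.265 and Tfap2c from −0.118 to 0.034, and with CsA in E9.5c5 Prdm1 ran from −0.23 to 0.874. The range was −2.647 to 0.407 for Dazl, E9.5c5 CsA against E9.5c5 FR10. Tfap2c for E9.5c5 against d4c7 ran from −0.191 to 0.218 and was −0.191 without the 3 libraries. The range was −0.131 to 0.555 for Etv4, difference of the CsA effect between the cell origins. Rcan1, CsA against FR10 averaged over both cell origins, ran from −0.272 to 0.139 and was 0.033 without the 3 libraries.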

Other observations

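The tests and values in this part were chosen after the data were seen, except the list tests.

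Among lists that passed in none of the 13 comparisons, 11 in all with a smallest camera adjusted p of 0.054, meiotic entry genes came closest. After culture in FR10, 4 of 8 rose and 0 fell, with a median log2 fold change of 1.42. The others were male germline fate, core pluripotency, DNA methylation enzyme, calcineurin, FGF receptor, cAMP response, cell cycle inhibitor, apoptosis, heat shock, and migration and adhesion genes. A further 3 lists had too few tested members for a test, namely blood and endothelial markers with 3, gonadal somatic markers with 1 and sex chromosome genes with 0. DNA methylation enzymes moved apart in day-4 PGCLCs against EpiLCs, with 3 of 12 higher and 4 lower, and with FGF2 against FR10, with 2 higher and 4 lower. Cell cycle inhibitors had a median of 1.14 in day-4 PGCLCs against EpiLCs, with 3 of 7 higher and 0 lower.

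Later germ cell genes differed between replicates of the embryo cultures. The median of replicate 2 minus replicate 1 was −1.38 in E9.5c5 FR10 and −1.24 in E9.5c5 CsA, with 15 of 15 genes lower in each. In d4c7 FGF10 the median was 0.38, with 15 of 15 higher in replicate 2. In the other 6 groups the median lay between −0.178 and 0.471, with genes on both sides. Dazl was at 694 and 93.7 RPM in the FR10 libraries and at 339 and 40 RPM in the CsA libraries. Feeder markers also differed between replicates, by −1.66 in d4c7 CsA and −2.03 in d4c7 FGF10. These are values without a test.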
